A study of Cicer arietinum with 8 samples.

How the data were processed

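The data were 48 image quantification files, 1 per channel of 24 arrays, and a table of the authors' processed ratios. Each of the 8 samples was a comparison of stressed with control tissue of a chickpea genotype and had 3 arrays, which the series design calls biological replicates, with RNA from pooled tissue. Most labels give 5 plants per group, and nothing more is said about how the pools were made. The p-values measure the spread between arrays. Group and tissue came from the labels. The dye and the role of each channel came from the file names, and the image names in the file headers give the same dyes.

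The deposited intensity values are mean pixel brightness per spot and in the local background, from ImaGene version 5.5 with automatic segmentation, per the file headers. Empty and poor spots were flagged by that software, per the file headers. The deposited table holds log2 values which, per the labels, are means over 3 biological replicates. The series design says that they were made in GeneSight by the authors after subtraction of local background, omission of flagged spots and LOWESS, with duplicate spots combined. Its centring is not stated, and its column medians were -0.0852 (drought leaves), 2e-04 (drought flowers), -0.123 (cold flowers), -0.12 (cold leaves), -0.25 (salt shoots, 24 h), -0.335 (salt roots, 24 h), -0.253 (salt shoots, 48 h) and -0.304 (salt roots, 48 h). Its direction was checked by regression of each column on the arrays' ratios of treated over control. With loess, all 22 coefficients were positive under both background settings looked at, and with median centring 21 of 22 were, the lowest at -0.13. The table was therefore read as treated over control. The size of the shift in its shifted logarithm stays unknown. It served only for a count of signs.

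Each array had 4704 spots in 24 subgrids of 196. There were 756 probes and 12 control probes with 6 spots each, and 96 unnamed spots. A probe was taken as above background in a channel where at least 50% of its spots had a mean above the local background mean plus 2 of its SDs. The count per channel ran from 162 to 581, and the number of unflagged spots from 602 to 2879. The Cy5-10T control was 32.2 to 102 times its background in the 24 channels named Cy5 and 1.46 to 2.80 times in the 24 named Cy3. These files were not compared with a genome, and the table of RefSeq genes given here shares no identifier with the probes.

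Background was corrected with normexp (offset 50) on the signal and background means, and each array was normalised with global loess in which controls and flagged spots had weight 0. Spots flagged in either channel were left out. Ratios were turned to stressed over control, so that array 3 of each condition changed sign, and the spots of a probe were averaged. A linear model was fitted per probe with limma 3.58.1 in R 4.3.3, with a coefficient per condition and a common dye term, and moderated with eBayes. Ratios and standard errors printed with the calls are from that model, and folds are 2 to the power of the fitted log2 ratio. A probe was tested in a condition with values on at least 2 of 3 arrays. P-values were adjusted by Benjamini-Hochberg over the probes of a condition, and the threshold was an adjusted p of 0.05. Differences between conditions were tested as contrasts within the same model. The dye term itself passed for 48 of 500 probes. Overlaps of calls were tested with Fisher's exact test, 2-sided, on probes tested in both conditions. Overlaps in the same direction were planned, and those in opposite directions were added after the data were seen.

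The design fixed before the data were examined was to fit all 24 arrays. The 3 arrays of salt roots at 24 h were found to be copies of 1 scan, rescaled or shifted, so they were averaged as 1 sample, which is below the minimum of 2 arrays, and the fit used the other 21 arrays. Of 8 planned differences, 6 were tested. Between any other channel files the share of spots with the same pixel SD was 0%. In array 3 of salt roots at 24 h, the 12 Cy5-10T spots had been exchanged between channels (median 46837 in the control channel, 922.36 in array 1), so the true dye orientation of that scan is not known. The file headers give a day of image quantification, 5 in all. The earliest held 1 array of drought leaves and 1 of cold leaves, too few for values within it, and was tried as a block. The block set only that day apart. Drought and cold arrays were all quantified on days 1 and 2, and salt arrays on days 3 to 5. Day therefore cannot be told apart from salt against the other stresses. Array 1 of salt shoots at 24 h was the only array of day 4. The copies of salt roots at 24 h carry days 5, 3 and 5.

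The 15 functional gene lists and marker lists fixed in advance select probes by words in a gene description. They matched 0 probes because the files hold no descriptions, so no list was tested, and classes of identifiers were counted in their place, a choice made after the data were seen. The rule for named probes, fixed in advance, takes in each condition the called probes changed the same way in every array with a value, ordered by size of change. It allowed 12 per direction and 5 for a difference, and only the first 2 are printed because the codes of the named probes carry no gene names.

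The functions were tested on simulated arrays with the real layout, flags and background, in which a random part of the 756 probes changed by 1.5, 2 or 3-fold per condition. Simulated changes of 2-fold were recovered at 75.0% in drought leaves (441 probes tested), 86.4% in drought flowers (434), 83.3% in cold flowers (433), 72.4% in cold leaves (429), 86.5% in salt shoots at 24 h (394), 76.7% in salt shoots at 48 h (419) and 70.4% in salt roots at 48 h (244). At 1.5-fold recovery was 38.0% in drought leaves, 45.0% in drought flowers and 55.6% in cold flowers. False calls were 2.6% to 7.79% of calls in these 7 simulated conditions. In drought leaves 50, 32 and 28 of the 441 tested probes were changed by 1.5, 2 and 3-fold. The noise was drawn independently for each array, with the model's own spread and dye term. Recovery may be lower where arrays disagree or fewer probes change, and the simulation did not cover such cases.

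Alternatives fixed in advance were background subtraction as in the study, no background correction, median centring, loess by subgrid, flagged spots kept, an offset of 10, no dye term, separate fits, a filter on dim probes (492 probes kept), the median over spots, each array left out, the replicate number as a block, scaling between arrays, array quality weights, the methods' t-test with its interval criterion, the authors' table and an added 2-fold threshold. Separate fits took a condition or a pair of conditions alone and held no dye term. Added after the data were seen were a rule that drops a spot only where both channels are flagged and a minimum of 3 unflagged spots. The quantification day as a block and tests of salt roots at 24 h as 1 or as 3 arrays were added then too.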

Results

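The series measured how a chickpea (Cicer arietinum) genotype changed its transcript levels under drought, cold and high salinity. RNA of stressed and unstressed plants was hybridised together to 2-colour cDNA arrays, on which each probe is a spotted cDNA and the ratio of the dyes compares stressed with control tissue on the same slide. There were 8 comparisons, each with 3 arrays. Drought was followed in leaves and in flowers with early pods when stressed pots had dried to 30% water content and control pots were held at 80%. Cold was followed in the same tissues after a week of nights at 5 °C. Salt was given as 150 mM NaCl to plants aged 18 days, and shoots and roots were collected 24 h and 48 h later. On 2 arrays of a comparison the stressed RNA carried the dye Cy5, and on array 3 the dyes were swapped.

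Each array held 756 probes other than controls, with 6 spots each. The files identify probes only by codes, without gene descriptions, so results are given by code and by the prefix of the code. There were 442 probes starting in U, 117 in CA, 156 in LS and 41 in LC. Some LC codes, such as LCLipoxR and LCCopaoxR, hold what may be an abbreviated gene name. The array design is known to carry chickpea, grass pea and lentil sequences, and the files used here do not tie a prefix to a species. Signal over background set what could be measured. Between 162 and 581 probes per channel lay above background, the lowest in the control channel of array 1 of salt roots at 48 h. LC probes were almost never above background, and only 2 of the 41 were tested in any condition. The number of arrays limits the precision of every value below.

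**Figure D1:**
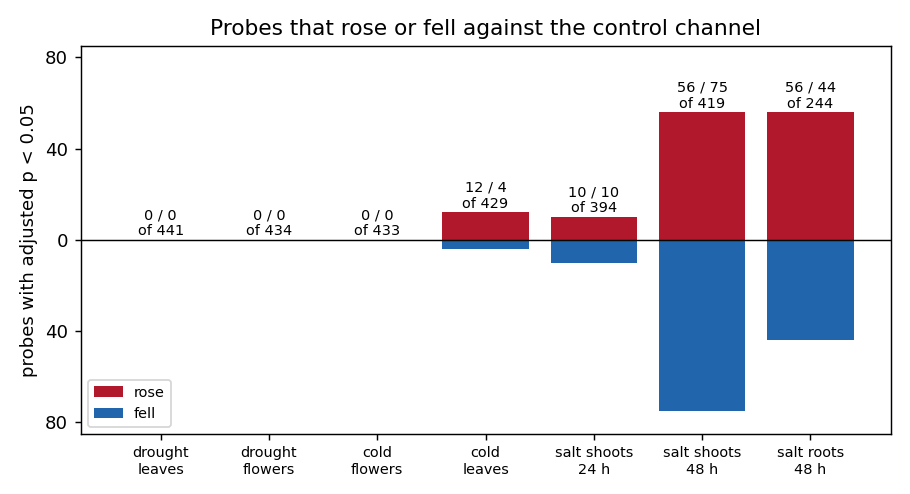
Number of probes that rose (red, upward) or fell (blue, downward) in each comparison with 3 separate arrays, at an adjusted p under 0.05 in limma, with the number tested above each bar. Salt at 48 h changed 131 of 419 probes in shoots and 100 of 244 in roots, against 0 to 20 probes in the other comparisons.

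In leaves of droughted plants, no probe passed the threshold among 441 tested with limma, and the smallest adjusted p was 0.0649. Fitted log2 ratios ran from -2.24 to 1.14 with a median size of 0.24. At an unadjusted p under 0.05 there were 78 probes, 38 higher and 40 lower, where 22.0 would pass by chance. The U and CA classes gave 0 calls among 292 and 97 probes, and the LS class 0 among 50. In flowers with early pods of the same treatment no probe passed among 434, the smallest adjusted p was 0.229, and 51 probes had an unadjusted p under 0.05, 16 higher and 35 lower, against 21.7 by chance. The methods' t-test, which takes each condition's arrays alone, gave 0 probes after adjustment in both tissues, with 32 in leaves and 12 in flowers before it. After adjustment it gave 0 in salt roots at 48 h too and 1 in salt shoots at 48 h. Its 0 calls therefore do not decide whether drought changed these probes. Array quality weights gave 4 calls in leaves. In flowers the count rose to 33 without array 3 and to 23 without array 2, over 191 and 194 tested probes.

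The leaf and flower responses to drought were compared directly, since the same stress was given to both. No probe differed among 389 tested with limma (smallest adjusted p 0.543), and 31 had an unadjusted p under 0.05. Across these probes, which are not independent replicates, the fitted log2 ratios of leaf and flower correlated with r = 0.33, close to the 0.32 between drought leaves and salt shoots at 48 h.

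Cold leaves had 12 probes that rose and 4 that fell among 429 tested. The largest rises were U070, 6.88-fold (log2 2.78 ± 0.48 SE, measured on 2 arrays of the same dye orientation at 1.59 and 2.89, adjusted p = 0.0435), and CA0897, 3.37-fold (log2 1.75 ± 0.33, higher on 3 of 3 arrays, adjusted p = 0.0114). The largest falls were U096, 2.29-fold (log2 -1.20 ± 0.29, lower on 3 of 3 arrays, adjusted p = 0.0435), and CA0689, 2.20-fold (log2 -1.14 ± 0.26, lower on 3 of 3 arrays, adjusted p = 0.0213). Of the U class 8 rose and 2 fell among 290, of the CA class 4 rose and 1 fell among 96, and of the LS class 1 fell among 43. U070 rested on spots unflagged in both channels, and its log2 ratio was 0.27 with flagged spots kept and 0.20 with a spot dropped only where both channels were flagged, neither past the threshold. U096 passed in 11 of 18 alternatives and not, for example, without array 1 (adjusted p = 0.202) or array 3 (0.408), and CA0689 passed in 14 of 18. The count of calls fell to 3 without array 1, 6 without array 3, 9 with the day of image quantification as a block and 0 when the condition was fitted alone.

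Cold flowers with early pods had no probe past the threshold among 433 tested with limma. The smallest adjusted p was 0.0544, and 51 probes, 25 higher and 26 lower, had an unadjusted p under 0.05, against 21.7 by chance. The methods' t-test gave 40 before adjustment and 0 after it, as it also did after adjustment in salt roots at 48 h. Calls appeared under other settings, up to 13 with array quality weights. Cold leaves and flowers did not differ at any of 388 probes in limma (smallest adjusted p 0.934), and 17 had an unadjusted p under 0.05. Their fitted log2 ratios correlated with r = 0.66 across probes, which are not independent replicates. In both tissues arrays 1 and 2, of the same dye orientation, correlated better with each other (0.74 in flowers, 0.49 in leaves) than with the swapped array. Those values were -0.10 and -0.09 in flowers and 0.13 and 0.16 in leaves. A dye effect peculiar to these arrays was not told apart from a shared response.

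Leaves were also compared between drought and cold, which were given to plants of the same stage. Among 403 probes, 6 were higher and 9 lower under drought than under cold, each relative to its own control. U096, which fell in cold leaves, had a drought response above its cold response by 2.18 on the log2 scale (SE 0.41, 6 arrays, adjusted p = 0.0123), and LS0551 by 2.00 (SE 0.46, 5 arrays, adjusted p = 0.0426). CA0897, which rose in cold leaves, had a difference of -1.98 (SE 0.46, 6 arrays, adjusted p = 0.0419), and U488 of -1.55 (SE 0.27, 5 arrays, adjusted p = 0.00898). The count was 2 without array 3 of drought leaves and 57 with scaling between arrays. It was 5 with flagged spots kept or without array 3 of cold leaves, 9 without array 2 of drought leaves, 3 without the dye term and 0 with the pair fitted alone. CA0897 lost its call on leaving out any of the 3 cold arrays or drought array 3 (adjusted p from 0.0500 to 0.145), and LS0551 passed in 14 of 20 alternatives. No flower probe differed between drought and cold among 415 tested in limma (smallest adjusted p 0.144, 47 at an unadjusted p under 0.05), and without drought flower array 2 or 3 there were 4 or 5.

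Salt at 24 h changed 20 of 394 probes in shoots, 10 up and 10 down. U278 rose 4.13-fold (log2 2.05 ± 0.22 SE, higher on 2 of 2 arrays with a value, adjusted p = 0.00643) and U098 rose 3.84-fold (log2 1.94 ± 0.49, 3 of 3 arrays, adjusted p = 0.0342). U076 fell 1.67-fold (log2 -0.74 ± 0.15, 3 of 3 arrays, adjusted p = 0.0129) and U219 fell 1.64-fold (log2 -0.71 ± 0.15, 3 of 3 arrays, adjusted p = 0.0162). The U class held 19 of the calls among 262 probes and the CA class 1 among 93, a difference with Fisher's exact test p = 0.0327 that did not pass after adjustment over 4 conditions (adjusted p = 0.131). None of 39 LS probes passed. All calls went when array 1 or array 3 was left out or the condition was fitted alone. Without the dye term 8 were made, with a minimum of 3 unflagged spots 35 and with array quality weights 121. Another normalisation moved the balance of the calls, to 10 up and 3 down with median centring and 9 up and 3 down with loess by subgrid.

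By 48 h of salt, 131 of 419 shoot probes had changed, 56 up and 75 down. U098 rose 12.0-fold (log2 3.58 ± 0.49 SE, adjusted p = 0.000233) and U034 rose 8.90-fold (log2 3.15 ± 0.46, adjusted p = 0.00052), both higher on 3 of 3 arrays. CA0705 fell 2.54-fold (log2 -1.35 ± 0.24, lower on 3 of 3 arrays, adjusted p = 0.00118) and LS0381 fell 2.45-fold (log2 -1.29 ± 0.23, lower on 2 of 2 arrays, adjusted p = 0.00358). Rises reached further than falls, with 25 called rises and 15 called falls of 2-fold or more. In the U class 37 rose and 50 fell among 276, in the CA class 19 rose and 19 fell among 94, and in the LS class 6 fell and 0 rose among 49. The share of calls did not differ between the U and CA classes (Fisher's exact test, adjusted p = 0.26). Between 51 and 114 probes were called with 1 array left out (51 without array 3, 59 without array 1), and 51 with the condition fitted alone. With median centring in place of loess, 68 rose and 59 fell.

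**Figure D2:**
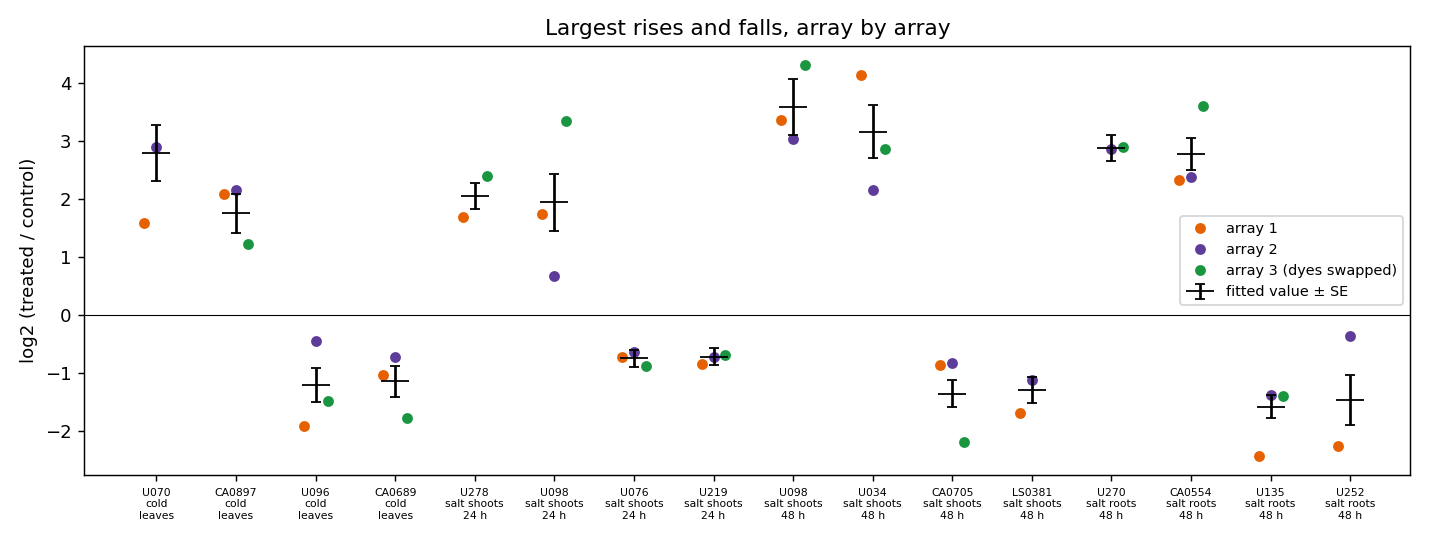
Log2 ratio of stressed over control for the 2 largest called rises and falls in each comparison with calls, where a point is 1 array, green marks the array with swapped dyes, and the bar is the fitted value ± SE from limma. Only probes with every array on the same side of 0 were eligible, and U098 in salt shoots at 48 h had the highest fitted value, 3.58.

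Shoots at 24 h and 48 h were set against each other to follow the response in time. Of 19 probes called at 24 h and tested at both times, 16 were called in the same direction at 48 h. There were 8 shared rises against 1.29 expected of independent lists (Fisher's exact test, adjusted p = 1.1e-05) and 8 shared falls against 1.91 (adjusted p = 0.000243). Separate fits left 0 of either, and the shared falls were 2 without the dye term, none past the threshold. Both lists came from the same fit, with a spread and dye term per probe in common, so they were not fully independent. Of 55 probes that rose at 48 h, 49 had a ratio above 0 at 24 h, and of 73 that fell, 59 were below 0 at 24 h. The difference between times passed in limma for 1 of 383 probes, CA0562, higher at 48 h by 1.79 on the log2 scale (SE 0.30, 5 arrays, adjusted p = 0.0257), and 75 had an unadjusted p under 0.05. CA0562 passed in 12 of 19 alternatives and not, for example, with median centring (adjusted p = 0.177), and it could not be tested without array 2 or 3 of 24 h. Array quality weights gave 14 probes.

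Salt at 48 h changed 100 of the 244 root probes tested, 56 up and 44 down. Loess centres the ratios of each array, so this balance is relative to the probes measured. Outside the test were 48 probes above background in the treated channel of every array and in the control channel of none. The reverse held for 0 probes. U270 rose 7.32-fold (log2 2.87 ± 0.22 SE, higher on 2 of 2 arrays, adjusted p = 9.01e-07) and CA0554 rose 6.82-fold (log2 2.77 ± 0.27, higher on 3 of 3, adjusted p = 2.27e-06). U135 fell 2.98-fold (log2 -1.58 ± 0.20, lower on 3 of 3 arrays, adjusted p = 2.83e-05) and U252 fell 2.75-fold (log2 -1.46 ± 0.43, lower on 2 of 2, adjusted p = 0.0213). The control signal of U252 was above background on only 1 array. The U class had 45 rises and 30 falls among 173 probes, the CA class 10 and 12 among 58, and the LS class 1 and 2 among 13. Of the 100 calls, 56 rested on 3 arrays and the others on 2, since the dim control channel of array 1 left many spots flagged. The count was 47 without array 2, 49 without array 3 and 63 with the condition fitted alone. It was 195 with a spot dropped only where both channels were flagged and 261 with flagged spots kept, over 454 and 756 tested probes.

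The 3 arrays deposited for salt roots at 24 h were not separate measurements. Outside the Cy5-10T control spots, the signals of array 2 equalled those of array 3 times 1.1234 in both channels to within 1e-05, and array 1 equalled array 3 plus 2.8357 in the control channel and plus 3.0123 in the treated channel. Spot positions were equal at 100% of spots and pixel SDs at 99.74%, against 0% in every other condition. The arrays were counted as 1 sample, with no test. Of 306 probes with a value, 45 were at least 2-fold higher than the control (14.7%, exact 95% binomial interval 10.9% to 19.2%) and 25 at least 2-fold lower (8.17%, 5.36% to 11.8%), the interval covering counting error over probes only. The lower share was 4.90% without background correction, 3.27% with scaling between arrays and 16.5% with a spot dropped only where both channels were flagged. The probes named at 48 h had log2 ratios of 2.38 for U270, 3.47 for CA0554 and -1.11 for U135 at 24 h. U252 had no ratio at 24 h, being above background in the control channel only. Of the probes that rose at 48 h, 48 of 54 with a value were above 0 at 24 h, and of those that fell, 36 of 41 were below 0. Over all 234 probes tested at 48 h with a value at 24 h, 157 (67.1%) had the same sign, and the ratios at both times correlated with r = 0.78, across probes that are not independent replicates. The 3 copies name the same channel as treated, and only their dye orientations conflict. The sign of the 24 h ratios rests on that labelling of the channels, and no dye effect was taken off them. With the ratio turned, the shares higher and lower would change places, the correlation with 48 h would be negative and the probes named would have the opposite sign. The planned tests of roots at 24 h against shoots at 24 h and against roots at 48 h were not made.

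**Figure D3:**
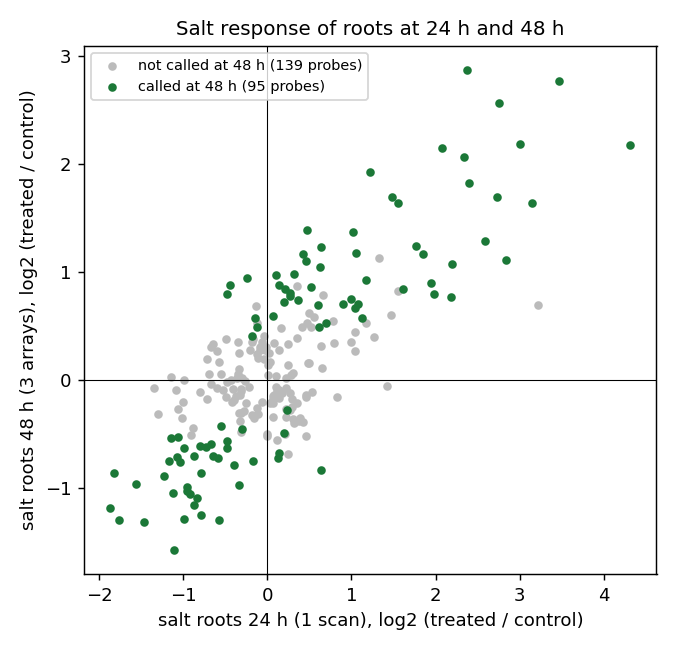
Log2 ratio of salt over control in roots at 24 h (horizontal, 1 scan) and at 48 h (vertical, fitted over 2 or 3 arrays), a point per probe, green where the probe passed the threshold at 48 h. Of the green probes, 48 of 54 that rose and 36 of 41 that fell at 48 h had a 24 h ratio of the same sign as labelled, against 157 of 234 over all points.

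Roots and shoots were compared at 48 h of the same treatment. The response differed at 61 of 236 probes, 31 higher and 30 lower in roots. U126 was higher in roots by 2.69 on the log2 scale (SE 0.42, 5 arrays, adjusted p = 0.000244), with a rise of 1.70 in roots and a fall in shoots (adjusted p = 0.0113). U350 was higher in roots by 2.67 (SE 0.24, 5 arrays, adjusted p = 3.62e-06), with 2.07 in roots and -0.60 in shoots. U098 had a lower response in roots, with a difference of -2.89 (SE 0.68, 6 arrays, adjusted p = 0.00449), from 0.69 in roots (adjusted p = 0.292) and 3.58 in shoots. The difference was not tested at 24 h. In the single 24 h root scan, as labelled, the log2 ratio of U098 was 3.22, with no dye term taken off. In shoots at 24 h the fitted value was 1.94 (SE 0.49), from the model with a dye term. These are unlike measures and do not decide about a difference at 24 h. U135 had a difference of -2.26 (SE 0.28, 6 arrays, adjusted p = 4.1e-05). Among the 31 probes higher in roots, 26 had fitted ratios of opposite sign in the 2 tissues, and among the 30 lower in roots 22, a share that selection on the difference favours. Over all 236 probes, 11 rose in roots and fell in shoots against 6.96 expected of independent lists (Fisher's exact test, adjusted p = 0.371), 5 went the other way against 8.76 (adjusted p = 0.432), and the ratios correlated across probes with r = 0.23. Of the probes tested in both tissues, 16 rose in both against 10.6 expected (Fisher's exact test, adjusted p = 0.118) and 6 fell in both against 5.78 (adjusted p = 1). The count was 32 without root array 2, 35 without root array 3, 145 with a spot dropped only where both channels were flagged and 200 with flagged spots kept.

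**Figure D4:**
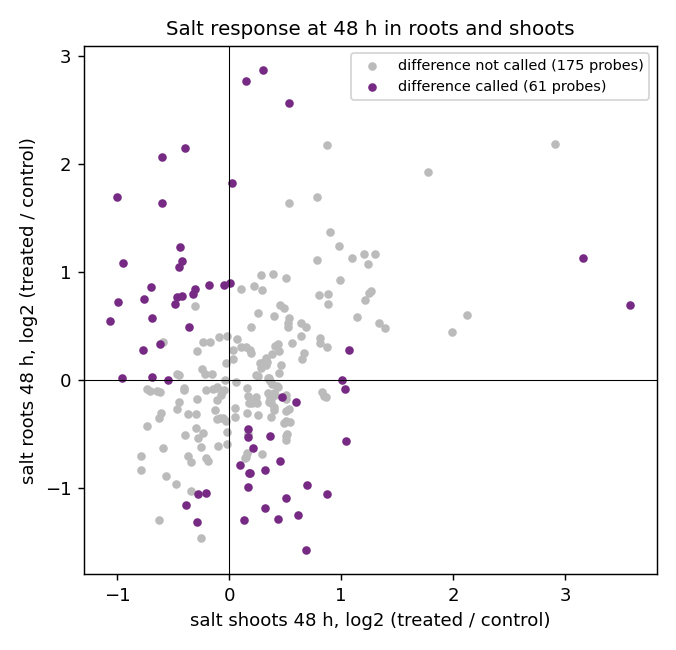
Log2 ratio of salt over control at 48 h in shoots (horizontal) and roots (vertical), a point per probe tested in both, purple where the difference between tissues passed the threshold in limma. The 61 purple points lie mostly in the quadrants of opposite sign, 26 of the 31 higher in roots and 22 of the 30 lower, which selection on the difference favours.

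Calls were also compared between the remaining conditions. The adjustment covered all 12 pairs and directions in which both had calls, those given above included. All lists came from the same fit, so they were not fully independent. Falls in salt shoots at 24 h and in salt roots at 48 h shared 6 probes against 1.49 expected (Fisher's exact test, adjusted p = 0.00253), and rises shared 4 against 1.59 (adjusted p = 0.118). The shared falls were 2 with median centring and 1 without the dye term, neither past the threshold. Cold leaves shared 1 rise and 2 falls with salt shoots at 48 h, against 1.52 and 0.77 expected (adjusted p = 1 and 0.337), and shared no call in the same direction with salt shoots at 24 h or salt roots at 48 h. In opposite directions, 4 of the 7 cold-leaf rises tested in salt roots at 48 h were called falls there against 1.28 expected (Fisher's exact test, adjusted p = 0.271), and U096 fell in cold leaves and rose in salt shoots at 24 h. Salt was not tested against drought or cold as a difference, because salt was given to young plants and the other stresses to flowering plants.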

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

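Of the tests below, the comparison of pixel SDs for salt roots at 24 h was chosen after the result was seen; the other tests were written down before their results were known. How the tests of spread and of a discordant array were read for conditions without calls was revised after their results were seen, because leaving out an array also ended all calls in salt shoots at 24 h, and because the highest spread had come from roots with large responses.

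Salt responses of roots and shoots at 48 h stood apart because the test of the difference itself passed at 61 of 236 probes. Low signal averaged over both channels and organs, as the whole cause, is argued against by the brightness of the probes. Of the brighter part of the tested probes 26.3% was called and of the dimmer part 25.4%, 118 probes each. The split does not rank probes by their root control signal, so low signal there is not decided. The dim control channel of root array 1 is argued against by the 55 calls made without that array. A biological difference between the organs stays open and was not tested apart from other differences between their arrays, such as separate slides for each organ. Other splits of the 6 arrays gave at most 6 calls, and with 10 splits no share under 0.05 can be reached, the real split being the 1 with the most.

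The change between 24 h and 48 h in shoots was listed because 1 of 383 probes differed in the test of the difference. Of the 10 splits of those 6 arrays, 2 gave as many calls and the highest other gave 3, and too few splits exist for a share under 0.05.

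Probes above background in the treated channel of every array and in the control channel of none were outside the comparisons, since none had the values on 2 arrays needed for a test. There were 48 of these in salt roots at 48 h (21 U, 10 CA and 17 LS), 5 of them with a ratio on 1 array, and 9 in salt shoots at 48 h, 1 of them with a ratio. The sets shared 1 probe. The reverse, control channel only, held for 0 probes in roots and 1 in shoots at 48 h. The control channels of the root arrays had 162, 335 and 243 probes above background and the treated channels 443, 404 and 406.

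Salt roots at 24 h had 3 arrays alike. Storage of 1 scan under 3 names is consistent with 99.74% of spots having the same pixel SD in all 3, where the highest share in any other condition was 0%. No biological explanation was tested, since the design gives none for equal pixel SDs. How the copies arose stays open.

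Drought leaves, drought flowers and cold flowers had no called probe. A larger spread between arrays is argued against in cold flowers, with a median SD over probes of 0.248. This lay below cold leaves (0.299), salt shoots at 48 h (0.291) and salt roots at 48 h (0.366). Drought flowers (0.266) lay below these too, which does not decide about spread there, because fewer of their probes had 3 arrays. These were 189 of 434 tested probes, against 319 of 433 in cold flowers and 308 of 429 in cold leaves. The fit also shares a spread per probe across conditions, so a condition's own SD sets its p-values only in part. Drought leaves (0.31) lay above cold leaves and salt shoots at 48 h and below salt roots at 48 h and salt shoots at 24 h (0.339, 20 calls), which does not decide about spread there. A single discordant array stays open in drought leaves and cold flowers, where leaving out any array gave 0 calls but array quality weights gave 4 and 13, and in cold flowers array 3 correlated with the others at -0.10 and -0.09 while those correlated at 0.74. In drought flowers it may play a part, since up to 33 probes were called with 1 array left out (array 3), though 23 were called without array 2 as well, so the test does not single out an array. A small response in these tissues stays open and was not tested.

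Turning the sign of 1 array at a time makes 4 orientations per condition, too few for a share under 0.05. The real orientation gave 131 calls in salt shoots at 48 h (highest other 1), 100 in salt roots at 48 h (highest other 39), 20 in salt shoots at 24 h (highest other 2) and 16 in cold leaves (highest other 3), and was the 1 with the most in each. In drought leaves, drought flowers and cold flowers all 4 orientations gave at least the 0 real calls, with highest others of 0, 1 and 0. For differences between drought and cold leaves the real split gave 15 calls, the highest other 1 and 1 of 10 splits as many. The differences with 0 calls (leaf against flower under drought and under cold, and flowers of drought against cold) had 0 as the highest other, so that all 10 splits gave as many.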

How the results depend on the processing

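Alternatives added after the data were seen were the rule that drops a spot only if both channels are flagged, the minimum of 3 unflagged spots, the quantification day as a block and the tests of salt roots at 24 h. All 25 printed values of named probes kept their direction in all 462 alternatives with a value, and 404 of these also passed the threshold. The naming rule favours a kept direction, since it takes the largest calls and, within conditions, only probes changed the same way in every array. Counts with 1 array left out ran from 3 to 11 in cold leaves, 0 to 33 in drought flowers, 0 to 0 in drought leaves and cold flowers, 0 to 21 in salt shoots at 24 h, 51 to 114 in salt shoots at 48 h and 47 to 83 in salt roots at 48 h. For differences they ran from 32 to 56 (roots and shoots, 48 h), 0 to 1 (shoot times), 2 to 19 (drought and cold leaves), 0 to 5 (drought and cold flowers) and 0 to 0 for leaf against flower under either stress. A left-out array also leaves fewer probes with the 2 values needed for a test.

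Counts that moved by over 1.5 times were as follows, and the cause was not tested unless stated. Scaling between arrays gave 1 call in drought leaves, 2 in drought flowers, 12 in cold flowers, 29 in cold leaves and 86 in salt shoots at 48 h. For differences it gave 1 between leaf and flower under drought, 57 between drought and cold leaves, 9 between drought and cold flowers and 0 between shoot times. Array quality weights gave 4 in drought leaves, 13 in cold flowers, 121 in salt shoots at 24 h and 14 between shoot times. The minimum of 3 spots gave 1 in drought leaves, 5 in cold flowers, 35 in salt shoots at 24 h, 0 between shoot times and 29 between drought and cold leaves. No background correction gave 6 in cold flowers and 0 between shoot times. The quantification day as a block gave 6 in cold flowers and 9 in cold leaves. Median centring gave 13 in salt shoots at 24 h and 0 between shoot times, and loess by subgrid 12 in salt shoots at 24 h, 1 between cold leaf and flower and 37 between drought and cold leaves. Without the dye term there were 8 in salt shoots at 24 h and 3 between drought and cold leaves. Separate fits had no dye term and 2 residual degrees of freedom at most per condition. They gave 0 in cold leaves and salt shoots at 24 h, 51 in salt shoots at 48 h and 63 in salt roots at 48 h. For shoot times and for drought and cold leaves they gave 0. The filter on dim probes gave 30 between drought and cold leaves.

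Keeping flagged spots gave 261 in salt roots at 48 h, 200 between roots and shoots, 0 between shoot times and 5 between drought and cold leaves, with all 756 probes tested. Dropping a spot only if both channels were flagged gave 195, 145, 0 and 5. Adding a 2-fold threshold left 9 in cold leaves, 6 in salt shoots at 24 h, 40 in salt shoots at 48 h and 40 in salt roots at 48 h, by construction. The methods' t-test with its interval criterion gave 0 in cold leaves, both salt shoot times and salt roots at 48 h. Of called probes with a value in the authors' table, 16 of 16 had the same sign there in cold leaves. In salt shoots 20 of 20 did at 24 h and 126 of 131 at 48 h. In salt roots at 48 h, 88 of 97 did. That table was made from the same arrays, and its direction was read from their ratios, so equal signs are not independent support. Salt roots at 24 h, with no test otherwise, gave 55 calls as 1 array with pooled spread, assumed to vary like other conditions, and 152 as 3 arrays taken as independent, which counts copies as replicates. On that footing 83 probes differed from shoots at 24 h and 41 from roots at 48 h. That fit of all 24 arrays, fixed in advance, also moved other counts, to 37 in salt shoots at 24 h, 2 in drought leaves, 3 in cold flowers and 53 between drought and cold leaves. The share of 24 h root probes at least 2-fold lower moved from 8.17% to 4.90%, 3.27% and 16.5% without background correction, with scaling and with the rule on both channels.

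Shared rises of salt shoots at 24 h and 48 h were 0 in separate fits, and shared falls 0 there and 2 without the dye term. Shared falls of salt shoots at 24 h and salt roots at 48 h were 2 with median centring, 3 with flagged spots kept, 1 without the dye term, 0 in separate fits and 5 with the rule on both channels. None of these passed. The replicate number as a block in place of the dye term gave 60 calls between roots and shoots at 48 h. It gave 1 between shoot times and 11 between drought and cold leaves, and moved no count by over 1.5 times. The block had terms common to all conditions, and number 3 is always the swapped array. It therefore still held the dye effect and did not model a pairing of arrays between conditions. The numbers were not taken to pair arrays, because same-numbered deviations correlated from -0.37 to 0.56, with a value of -0.086 or lower in each difference, and at most 3 of 6 arrays correlated best with their own number. The alternatives for gene lists were not run, since no list matched a probe. Signal over background limits the roots most, where 244 of 756 probes were testable at 48 h.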

Other observations

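Tests in this part were chosen after the data were seen. Some probes were above background in shoots, leaves and flowers and not in roots. In every channel of shoot, leaf and flower arrays (36 channels) and in no root channel (8 channels, the 24 h scan counted once), 10 probes were above background, 6 of class U and 4 of class CA. Between shoots and roots alone, 22 probes were above background in all 12 shoot channels and in none of the 8 root channels. No probe showed the reverse of either pattern. A root channel also had the fewest probes above background, 162, so dim root signal was not told apart from absent expression. Of the 10 probes, 3 fell and 0 rose in salt shoots at 48 h, against 72 falls and 56 rises among the other 409 tested (Fisher's exact test for falls, p = 0.394). No probe was above background in every leaf channel and in no flower channel, or the reverse, and 106 were above background in all 44 channels.

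The signal of the NORMCON control spots was 3.35 to 58.6 times background outside roots and 1.02 to 1.21 times in every root channel, stressed and control alike. The NEGCON spots were at 0.747 to 1.21 times background throughout. The files do not say what sequence NORMCON holds.

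In cold flowers, cold leaves and salt shoots at 24 h the swapped array stood apart. Arrays 1 and 2, which share an orientation, correlated across probes with r = 0.74 in cold flowers, 0.49 in cold leaves and 0.78 in salt shoots at 24 h, while the swapped array correlated with them at -0.10 and -0.09 in cold flowers, at 0.13 and 0.16 in cold leaves and at 0.23 and 0.01 in salt shoots at 24 h. After the common dye term was taken off, the values with the swapped array were 0.11 and 0.13 in cold flowers (0.67 between arrays 1 and 2). They were 0.39 and 0.32 in cold leaves (0.36 between arrays 1 and 2) and 0.45 and 0.18 in salt shoots at 24 h (0.74). In salt shoots at 48 h they were 0.66 and 0.69 before and 0.80 and 0.86 after, with 0.78 between arrays 1 and 2 before. In the other conditions arrays 1 and 2 did not correlate best. They correlated at 0.02 in drought leaves, 0.57 in drought flowers and 0.66 in salt roots at 48 h, and the higher value with the swapped array was 0.51, 0.58 and 0.72.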
